A study of Daucus carota with 6 samples.

How the data were processed

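RNA came from fleshy roots of betanin-accumulating transgenic carrots (BC, 3 samples) and of non-transgenic carrots (WT, 3 samples), and mRNA libraries were made with random hexamer priming and circularised, per the labels' protocols. The authors deposited 1 table for the whole series with an FPKM value per gene and sample, rounded to 2 decimals, together with protein descriptions, GO terms and KEGG pathways. RSEM was named in the submitters' processing notes, with no version. The aligner, the genome build and the gene annotation are not given in the sources used here, and RSEM divides reads shared by similar genes between them, so values of near-identical genes are uncertain. Among the tested genes 132 had the same 6 values as another tested gene, 56 of them called.

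The table held 35073 genes, 32113 with a locus ID and 2960 with a numbered ID of another kind, here called numbered IDs, and 7329 genes were at 0 in all 6 samples. A protein description was given for 33810 genes from NR and an informative one for 17147, a GO term for 22288 and a KEGG pathway for 7208. Of 21210 genes whose NR description carried a RefSeq protein accession, 18698 matched a RefSeq gene of the DH1 v3.0 assembly, which was used for names, for which genes lie next to each other and for the gene spans of 1 check in the closing section. Each sample column was matched to its sample by the sample's own description. FPKM are not counts, no gene lengths were used, and RSEM estimates need not be whole reads, so depth is unknown and no counting interval can be given. The FPKM summed to 1186760, 1141950 and 1153580 in WT replicates 1 to 3 and to 1287460, 1268930 and 1184880 in BC replicates 1 to 3. The most common ratio of low values to those of WT replicate 1 was 0.993 in WT replicates 2 and 3 and BC replicates 1 and 2 and 1.05 in BC replicate 3, a rough measure of relative depth.

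Genes with at least 1 FPKM in at least 3 samples (21033) were fitted as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), BC minus WT, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05, and a second count took genes changed at least 2-fold. Fold changes on this scale understate the changes of low genes. Lists of genes (39, of which 38 had at least 5 tested members) were fixed as search words for descriptions before the data were examined, as were the tests of genes, lists and terms, the rule for named genes and the alternatives, apart from those said to have been added later. The words also caught some genes of other function, which were kept. Lists were tested against the other genes by camera with a preset correlation of 0.01 and with an estimated one, and by fry. Terms with 10 to 500 genes were tested by one-sided Fisher's exact tests against the tested genes with any term.

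Named genes were the 8 called genes with the largest and the 8 with the smallest log2 fold change that had an informative description, a group mean of at least 5 FPKM and no overlap between groups. To these were added, per list, the called members with the largest and smallest change and the most abundant member, and all called members with a group mean of at least 5 FPKM in the carotenoid, general phenylpropanoid and tyrosine lists. Not every gene that the rule takes is printed. Genes named outside the rule are said to have been chosen after their values were seen.

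The fit was tested on simulated data for BC against WT over 21033 genes. It recovered 10%, 64%, 84% and 96% of 50 genes each changed by 0.5, 1, 2 and 3 on the log2 scale, with 10 false calls among 20833 unchanged genes, and called 0 of 50 random unchanged lists. Simulated genes varied independently, so the list result does not cover genes that move together. Only 200 genes were changed, while 46.4% of the tested genes were called in the data, so the recovered shares need not hold there.

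Alternatives were other pseudocounts (0.1 and 5), no filter and a filter at 5 FPKM, samples rescaled to equal totals, median-ratio size factors, quantile normalization, eBayes without a trend or robust, the replicate number as a block, and each sample left out in turn. Fits without genes read in one group only and without the genes with numbered IDs were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.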

Results

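Gene expression was measured by RNA-seq in the fleshy roots of carrot (Daucus carota). The 6 samples fell into 2 groups of 3, roots of transgenic carrots that carry betalain synthesis genes and accumulate the red pigment betanin (BC) and roots of non-transgenic carrots (WT). Levels are given as FPKM, a fragment count scaled for transcript length and library size, and as mean ± SD over 3 samples. The introduced genes, named CYP76AD1S, cDOPA5GTS and DODA1S in the labels, serve betalain synthesis. Values above 0 were listed for 24137, 24257 and 24178 genes in WT replicates 1 to 3 and for 25274, 25035 and 24954 genes in BC replicates 1 to 3. Pearson correlations of log2(FPKM + 1) across genes were 0.974 to 0.988 within WT, 0.953 to 0.979 within BC and 0.826 to 0.853 between the groups. The read depth behind these values is unknown, and the labels do not say whether the samples of a group came from separate plants, so the p-values measure only the spread between these samples.

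**Figure D1:**
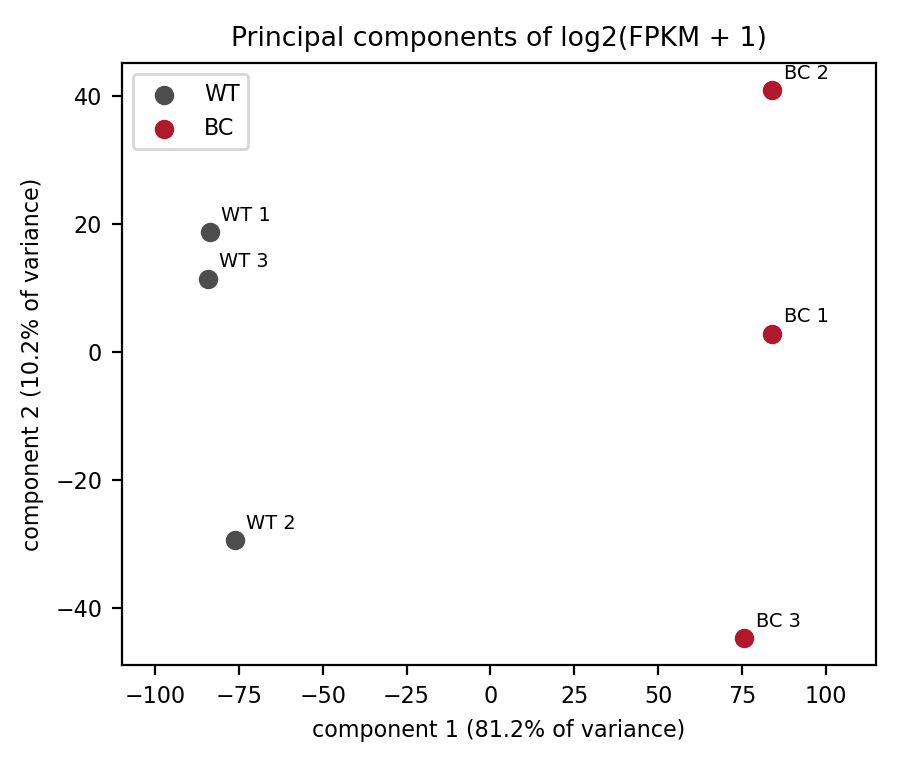
Principal components of log2(FPKM + 1) over the tested genes, each point being 1 root sample, with component 1 on the horizontal and component 2 on the vertical axis. Component 1 held 81.2% of the variance and separated the 3 BC from the 3 WT samples, and BC replicates 2 and 3 lay at opposite ends of component 2, which held 10.2%.

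The comparison of BC with WT roots asked which genes differ in expression between carrots that make betanin and carrots that do not. Photosynthesis genes were mostly higher in BC roots (59 of 81 tested rose, 6 fell), as were fatty acid desaturases (20 of 26 rose, 2 fell). Where they changed, genes of flavonoid synthesis (15 of 30 rose, 2 fell) and of nitrogen and sulfur uptake (19 of 43 rose, 4 fell) were also mostly higher. Spliceosome genes were mostly lower where they changed (105 of 216 fell, 12 rose). Genes for phytoene synthase, phenylalanine ammonia-lyase and polyphenol oxidase were higher in BC, and a copper-zinc superoxide dismutase gene was lower. Calls of some phenylalanine ammonia-lyase and polyphenol oxidase genes were lost when a sample was left out. Of 21033 genes tested with limma, 9749 (46.4%) passed a Benjamini-Hochberg adjusted p of 0.05, 4806 higher and 4943 lower in BC. The split was 4060 higher and 5652 lower with samples rescaled to equal totals, and 4306 and 6023 with quantile normalization. Changes of at least 2-fold were found for 4183 genes, 2663 higher and 1520 lower (2234 and 1901 with quantile normalization). The values of the 3 BC and the 3 WT samples did not overlap for 12004 genes (57.1%), against 10% by chance with 3 and 3 samples. The number of genes lower in BC was 3193 without WT replicate 3, and with a pseudocount of 5 the number changed at least 2-fold was 2304. With the stricter filter on low values 1749 genes were at least 2-fold higher.

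Among genes that the rule for named genes takes, which asks for an informative description, the 8 largest rises included 2 extensin-type genes, a defensin and an importin. An extensin, a structural glycoprotein of the cell wall (DCAR_030610.v1.0), rose from 3.48 ± 2.92 FPKM in WT to 669.7 ± 329.8 FPKM in BC, a log2 fold change of 7.31 (SE 0.53). An extensin-related proline-rich protein (DCAR_024247.v1.0) rose from 74.8 ± 19.2 to 8749 ± 3873 FPKM, a log2 fold change of 6.76 (SE 0.39, adjusted p = 3.61e-05, limma with Benjamini-Hochberg). The NDR1-like gene DCAR_008386.v1.0 rose from 0.0333 ± 0.0577 to 126 ± 9.26 FPKM, and the BURP domain gene DCAR_004509.v1.0 from 0.0767 ± 0.0115 to 64.4 ± 7.495 FPKM. A gene described as a partial beta subunit of ATP synthase (novel756) rose from 0.0167 ± 0.0289 to 114 ± 19.3 FPKM. Defensin-like protein 1 (DCAR_028972.v1.0) and an importin alpha-like gene (DCAR_027090.v1.0) were listed at 0 in all 3 WT samples and reached 129 ± 89.0 and 63.8 ± 14.2 FPKM in BC. The NDR1-like, BURP domain, ATP synthase, defensin and importin genes all belong to the genes read in one group only. That set, treated in the closing section, may reflect a difference in genome sequence between the plants.

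Under the same rule, the largest falls included a MADS-box gene described as agamous-like AGL27 (DCAR_024671.v1.0), a family of transcription factors that acts in flowering, which fell from 125 ± 13.8 FPKM to 0.0367 ± 0.0635 FPKM (log2 fold change -6.92, SE 0.13, adjusted p = 8.10e-07, limma with Benjamini-Hochberg). A second gene described as AGL27 (DCAR_026451.v1.0), chosen for mention after its values were seen, rose from 0.05 ± 0.05 to 55.8 ± 1.98 FPKM. It belongs to the genes read in one group only, as do the RICESLEEPER 2-like, Myb family, SLAH3-like and S24-1 genes below. The first AGL27 gene and the tankyrase-2-like gene below are outside that set, but their BC means were also near 0. The question of a difference in genome sequence applies to them too. A phloem protein 2-like A1 gene (novel381) fell from 96.9 ± 60.1 to 1.54 ± 2.67 FPKM, an ankyrin repeat gene (novel562) from 71.7 ± 7.15 to 0.523 ± 0.240 FPKM and a tankyrase-2-like gene (DCAR_015009.v1.0) from 47.4 ± 6.60 to 0.0567 ± 0.0551 FPKM. A RICESLEEPER 2-like zinc finger gene (novel1389) and a Myb family gene (novel1557) were at 43.6 ± 3.14 and 34.8 ± 0.972 FPKM in WT and at 0.0300 ± 0.0520 and 0.0400 ± 0.0458 FPKM in BC. An anion channel SLAH3-like gene (novel1242) and a 40S ribosomal protein S24-1 gene (novel773) were at 36.0 ± 4.86 and 36.4 ± 1.90 FPKM in WT and were listed at 0 in all 3 BC samples.

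**Figure D2:**
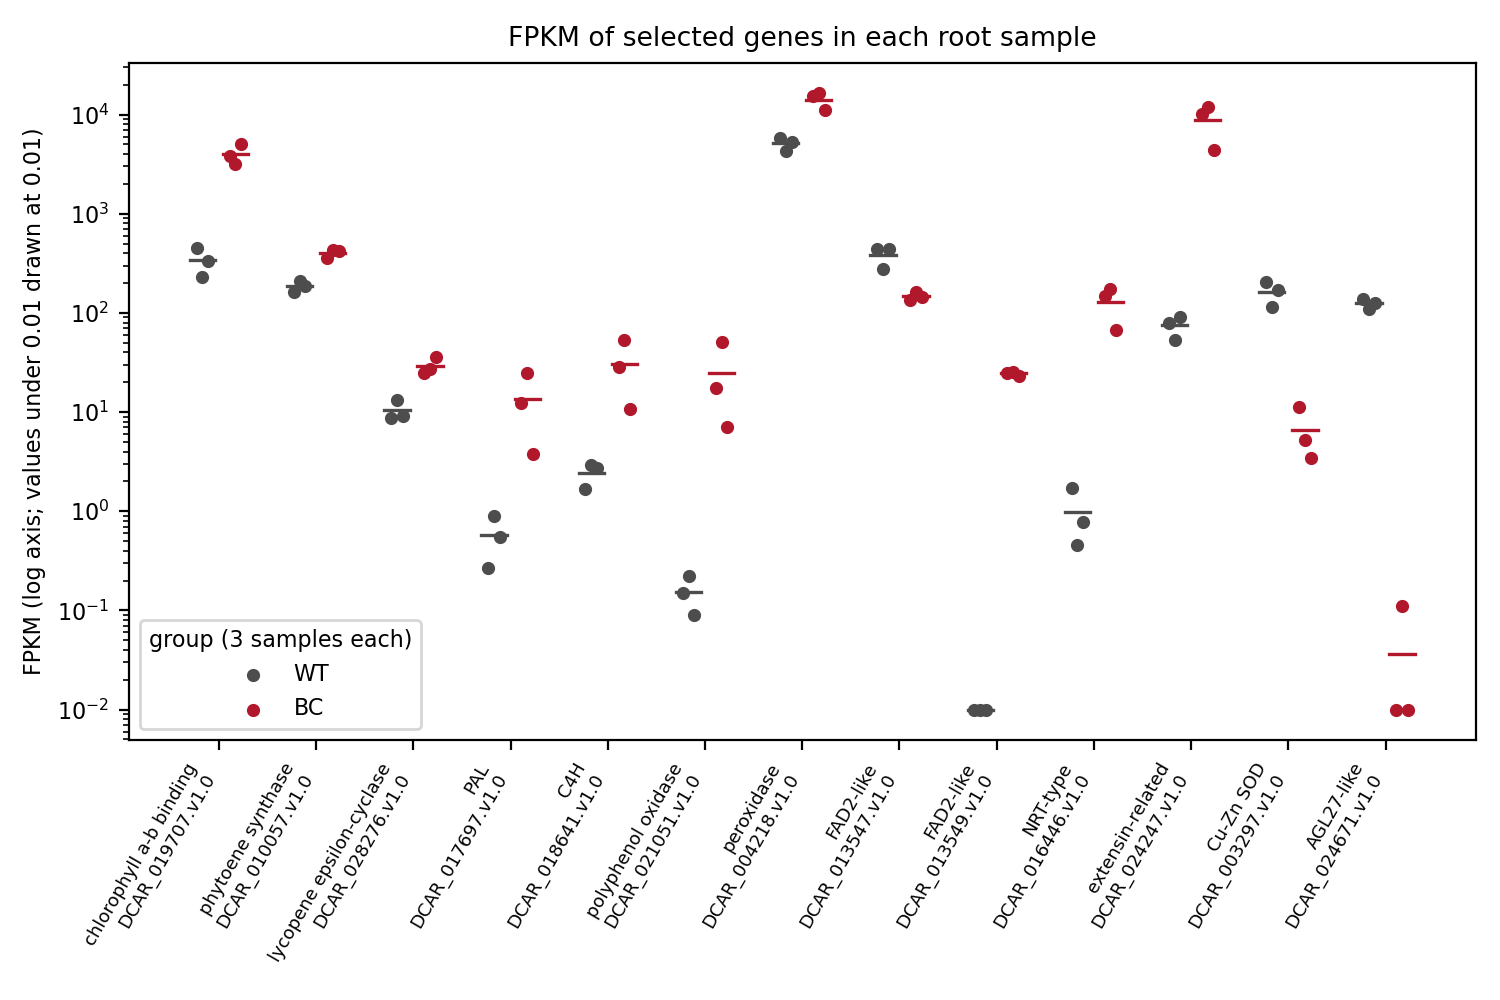
FPKM of 13 genes named in the text on a log axis, each point being 1 sample, with WT in grey and BC in red and a line at the mean of each group of 3. The chlorophyll a-b binding gene DCAR_019707.v1.0 had a mean of 339.5 FPKM in WT and 4014 FPKM in BC.

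Photosynthesis genes, fixed beforehand as a marker of green tissue, were mostly higher in BC roots. Of 81 tested, 59 rose and 6 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 1.23. Chlorophyll a-b binding protein 37 (DCAR_019707.v1.0), a light-harvesting protein, rose from 339.5 ± 114 to 4014 ± 981 FPKM (log2 fold change 3.59, SE 0.29). Another chlorophyll a-b binding gene (novel538) rose from 4.38 ± 3.52 to 88.8 ± 20.8 FPKM. In the opposite direction, an oxygen-evolving enhancer 3-1 gene (DCAR_024925.v1.0) fell from 12.2 ± 1.05 to 0.0700 ± 0.121 FPKM. Against the other genes the list was higher by camera with a preset correlation (adjusted p = 6.93e-10, limma with Benjamini-Hochberg), and the call was lost with an estimated correlation (adjusted p = 0.863 with an estimated correlation). The same loss applied to the 5 other lists that camera called. Of the 10 ways to part the 6 samples into 3 and 3, 7, the real one included, gave at least 6 called lists, with up to 11. The other groupings mix BC and WT samples and still carry part of their difference, so this count does not measure chance. Medians of the 6 lists were largest in size in the real grouping. For photosynthesis it was 1.23 against at most 0.63, and for cytochrome P450 0.44 against at most 0.35. Mixing shrinks the difference and the lists were chosen by the real grouping, so that is no test either. By fry, which tests whether members move one way on balance and does not compare them with other genes, 14 of the 38 lists passed, and all 38 passed its test for change in either direction.

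Fatty acid desaturases, which in carrot include enzymes of polyacetylene synthesis, rose in 20 and fell in 2 of 26 tested members (22 and 2 when adjusted over the list alone), with a median log2 fold change of 1.15. The FAD2-like gene DCAR_013549.v1.0 was listed at 0 in all 3 WT samples and was at 24.5 ± 1.33 FPKM in BC. Another FAD2-like gene (DCAR_013547.v1.0) fell from 386 ± 96.1 to 148 ± 14.9 FPKM, and the most abundant one (DCAR_019845.v1.0) was at 820.0 ± 123 FPKM in WT and 670.4 ± 48.5 FPKM in BC and did not pass the test, except with quantile normalization (adjusted p = 0.0264) and without WT replicate 2 (adjusted p = 0.0361, limma with Benjamini-Hochberg). A called member described as a cyclin-dependent kinase (DCAR_027654.v1.0), chosen for mention after its values were seen, has no known part in desaturation. The list had an adjusted p of 7.81e-05 by camera in limma with Benjamini-Hochberg adjustment and 0.863 with an estimated correlation.

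Genes of the general phenylpropanoid pathway, which turns phenylalanine into precursors of lignin and flavonoids, rose in 6 and fell in 1 of 12 tested members (6 and 2 adjusted over the list alone, 6 and 3 with quantile normalization). Phenylalanine ammonia-lyase, the entry enzyme, rose from 0.573 ± 0.316 to 13.6 ± 10.5 FPKM for DCAR_017697.v1.0, from 0.597 ± 0.240 to 9.58 ± 6.37 FPKM for DCAR_014989.v1.0 and from 0.587 ± 0.136 to 6.60 ± 4.67 FPKM for DCAR_020833.v1.0. Trans-cinnamate 4-monooxygenase (DCAR_018641.v1.0) rose from 2.42 ± 0.666 to 30.8 ± 21.1 FPKM (log2 fold change 2.98, SE 0.52), while a second gene of that name (DCAR_027611.v1.0) fell from 3.40 ± 0.208 to 0.670 ± 0.332 FPKM. The 4-coumarate CoA ligase genes DCAR_021385.v1.0 and DCAR_022233.v1.0 rose to 11.5 ± 6.60 and 22.1 ± 5.78 FPKM from 1.09 ± 0.475 and 9.85 ± 1.34 FPKM. Both matched the same RefSeq gene, so they may not be separate observations. The BC samples differed among themselves, with replicate 2 highest and replicate 3 lowest for 5 of the 6 members raised at least 2-fold, an order seen in 32.8% of all 2663 genes raised that much. Counts of this order, here and for other lists, were not fixed beforehand, and members that move together are not independent. The call for DCAR_020833.v1.0 was lost without BC replicate 1 (log2 fold change 1.93, adjusted p = 0.0559, limma with Benjamini-Hochberg), and the list as a whole did not pass camera (adjusted p = 0.511).

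Of 39 tested genes of lignin synthesis 17 rose and 4 fell (18 and 4 adjusted over the list alone), with a median log2 fold change of 0.57. A laccase (DCAR_012271.v1.0) was at 0.107 ± 0.0611 FPKM in WT and 13.4 ± 12.5 FPKM in BC, and its call was lost without WT replicate 1, WT replicate 3 or BC replicate 1 (adjusted p = 0.0513, 0.0560 and 0.0683, limma with Benjamini-Hochberg). Cinnamoyl-CoA reductase 1-like DCAR_012280.v1.0, of the branch toward monolignols, fell from 71.2 ± 4.53 to 8.09 ± 2.19 FPKM. The most abundant member was a nascent polypeptide-associated complex gene (DCAR_010571.v1.0), which does not make lignin, at 225 ± 3.24 FPKM in WT and 232 ± 13.6 FPKM in BC. The list passed camera with an adjusted p of 0.0282 (limma with Benjamini-Hochberg), and the adjusted p was 0.863 with an estimated correlation. It was 0.173 with a stricter filter on low values, 0.0641 without genes that have numbered IDs in place of locus IDs, 0.0533 without WT replicate 2 and 0.0761 without BC replicate 2, within a range from 0.00209 to 0.173 over the settings with the preset correlation (limma with Benjamini-Hochberg).

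Class III peroxidases, secreted enzymes that use hydrogen peroxide, rose in 9 and fell in 1 of 20 tested members (10 and 1 adjusted over the list alone). Peroxidase 42 (DCAR_004218.v1.0), among the most abundant transcripts, rose from 5140.3 ± 820.5 to 14199 ± 2816 FPKM, a call lost when no filter on low values was applied (adjusted p = 0.0646, limma with Benjamini-Hochberg). A peroxidase 12-like gene (DCAR_014452.v1.0) rose from 30.9 ± 2.74 to 591 ± 343 FPKM. BC replicate 2 was highest and BC replicate 3 lowest for 6 of the 8 members raised at least 2-fold, against 32.8% of all genes raised that much. The list did not pass camera (adjusted p = 0.113), but passed with samples rescaled to equal totals (adjusted p = 0.0415), with no filter (0.0369), with the stricter filter (0.0453), without numbered IDs (0.0136) and without BC replicate 3 (0.0361, limma with Benjamini-Hochberg). With an estimated correlation its adjusted p by camera was 0.863.

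Genes of flavonoid and anthocyanin synthesis rose in 15 and fell in 2 of 30 tested members, also when adjusted over the list alone, with a median log2 fold change of 0.69. A flavonol sulfotransferase-like gene (DCAR_030966.v1.0) rose from 0.433 ± 0.278 to 10.9 ± 2.89 FPKM. The most abundant member, an isoflavone reductase homolog (DCAR_001569.v1.0), was at 185 ± 22.5 and 402 ± 125 FPKM, and lost its call without BC replicate 1 (adjusted p = 0.0518, limma with Benjamini-Hochberg). BC replicate 2 was highest and BC replicate 3 lowest for 6 of the 13 members raised at least 2-fold. A putative dihydroflavonol-4-reductase (DCAR_019460.v1.0) fell from 9.09 ± 2.04 to 1.02 ± 1.53 FPKM. The list had an adjusted p of 0.0146 by camera in limma with Benjamini-Hochberg adjustment and 0.863 with an estimated correlation.

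Tyrosine and DOPA metabolism is the source of the betanin precursors. Of 12 tested members 3 rose and 2 fell, also when adjusted over the list alone, and the 3 that rose were polyphenol oxidases, which oxidise phenols such as DOPA. Polyphenol oxidase DCAR_021051.v1.0 rose from 0.153 ± 0.0651 to 24.99 ± 22.6 FPKM, with a log2 fold change of 4.10 (SE 0.61). BC replicate 2 was highest and BC replicate 3 lowest for 2 of these 3 genes. The calls of 2 others, DCAR_019633.v1.0 (7.93 ± 6.47 and 25.2 ± 3.34 FPKM) and DCAR_019634.v1.0 (0.15 ± 0.108 and 6.57 ± 6.13 FPKM), were lost without BC replicate 1 (adjusted p = 0.0707 and 0.0815) and without WT replicate 1 (adjusted p = 0.0698 and 0.0679, limma with Benjamini-Hochberg). The call for DCAR_019633.v1.0 was also lost without BC replicate 2 or 3 (adjusted p = 0.0525 and 0.0703). That for DCAR_019634.v1.0 was lost without WT replicate 2 or 3 (adjusted p = 0.0635 and 0.0650), with a pseudocount of 5 (adjusted p = 0.0551) and with quantile normalization (adjusted p = 0.0697, limma with Benjamini-Hochberg). Arogenate dehydrogenase (DCAR_014910.v1.0), the last step to tyrosine in plants, fell from 26.9 ± 3.41 to 18.5 ± 0.589 FPKM, a call lost without WT replicate 3 (adjusted p = 0.0580, limma with Benjamini-Hochberg). Homogentisate phytyltransferase DCAR_017980.v1.0 fell from 65.0 ± 7.64 to 43.9 ± 8.90 FPKM, a call lost without WT replicate 2 or 3 or BC replicate 1 or 2 (adjusted p = 0.0879, 0.0945, 0.0541 and 0.0558, limma with Benjamini-Hochberg). The carrot gene described as a DOPA dioxygenase (DCAR_017114.v1.0), chosen for mention after its values were seen, was at 34.7 ± 3.77 and 48.6 ± 13.6 FPKM and did not pass the test. In this list 2 members rose and 0 fell without WT replicate 3, and 1 rose and 1 fell without BC replicate 1. No description in the table named a betalain transgene or a selection marker, and the introduced genes were not analysed here.

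In the shikimate pathway, which supplies the aromatic amino acids, 8 of 33 tested genes rose and 5 fell, also when adjusted over the list alone, against 5 and 6 with samples rescaled to equal totals and 5 and 4 without WT replicate 3, BC replicate 1 or BC replicate 2. A gene for its first enzyme (DCAR_011674.v1.0) fell from 128 ± 7.91 to 51.3 ± 6.41 FPKM. A bifunctional dehydroquinate dehydratase and shikimate dehydrogenase gene (DCAR_001933.v1.0) rose from 0.0967 ± 0.0737 to 4.25 ± 2.72 FPKM.

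Carotenoid synthesis genes changed in both directions, with 7 of 21 tested higher and 5 lower, also when adjusted over the list alone. Phytoene synthase, the entry enzyme of the pathway, rose from 187 ± 24.5 to 403 ± 43.0 FPKM for DCAR_010057.v1.0 and from 8.85 ± 2.37 to 21.3 ± 3.57 FPKM for DCAR_023043.v1.0. Lycopene epsilon-cyclase (DCAR_028276.v1.0), of the branch toward alpha-carotene and lutein, rose from 10.4 ± 2.52 to 29.4 ± 5.74 FPKM, and beta-carotene hydroxylase DCAR_014519.v1.0 from 0.377 ± 0.159 to 12.8 ± 4.59 FPKM. Rises were also found for zeaxanthin epoxidase (DCAR_025735.v1.0, log2 fold change 0.55), a beta-carotene 3-hydroxylase (DCAR_020269.v1.0, log2 fold change 0.44) and an ABA DEFICIENT 4-like gene (DCAR_025914.v1.0, log2 fold change 1.74). Genes described as desaturation enzymes were among those that fell, with log2 fold changes of -0.82 for phytoene dehydrogenase DCAR_000109.v1.0, -0.38 for phytoene desaturase DCAR_016085.v1.0 and -0.37 for zeta-carotene desaturase DCAR_025321.v1.0. A further hydroxylase (DCAR_009395.v1.0) and a second ABA DEFICIENT 4-like gene (DCAR_017191.v1.0) had log2 fold changes of -0.57 and -0.46. The call for DCAR_016085.v1.0 was lost without WT replicate 3 (adjusted p = 0.0519) and that for DCAR_017191.v1.0 without WT replicate 1 or 2 or BC replicate 1 or 3 (adjusted p = 0.0793, 0.0651, 0.0844 and 0.0604, limma with Benjamini-Hochberg).

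Among other isoprenoid genes, 4 of 21 of the plastid MEP pathway rose and 5 fell (2 and 5 adjusted over the list alone), and 1-deoxy-D-xylulose-5-phosphate synthase 2 (DCAR_014178.v1.0) fell from 97.8 ± 28.7 to 37.6 ± 4.83 FPKM. In the mevalonate and sterol pathway 5 of 27 rose and 4 fell, with a squalene monooxygenase-like gene (DCAR_026887.v1.0) at 0.0900 ± 0.0173 and 5.71 ± 0.939 FPKM. Of 21 terpene synthases 8 rose and 2 fell, among them a beta-bisabolene synthase-like gene (DCAR_017536.v1.0) that rose from 0.343 ± 0.0757 to 13.2 ± 3.53 FPKM and a myrcene synthase-like gene (novel3944) that fell from 4.33 ± 0.962 to 0.437 ± 0.174 FPKM. Carotenoid cleavage and ABA synthesis genes rose in 1 and fell in 2 of 7, and in this list the median log2 fold change (-0.33) and the mean (0.25) differed in sign. Counts adjusted over the list alone were the same for these last 3 lists. The MEP counts were 2 and 7 with samples rescaled to equal totals, 2 and 4 without WT replicate 1 or BC replicate 3, 1 and 4 without WT replicate 3 and 1 and 5 without BC replicate 1. Mevalonate and sterol genes numbered 4 higher and 2 lower without WT replicate 1 or BC replicate 1 and 3 and 2 without WT replicate 3. For terpene synthases the counts were 6 and 3 with quantile normalization, 5 and 2 without WT replicate 1 and 4 and 2 without WT replicate 3 or BC replicate 1. For carotenoid cleavage they were 1 and 0 without WT replicate 3.

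Genes of nitrogen and sulfur uptake, a list that by its wording also took in phosphate transporters, rose in 19 and fell in 4 of 43 tested members, also when adjusted over the list alone, against 12 and 3 without WT replicate 3 and 13 and 2 without BC replicate 1. The high-affinity nitrate transporter 3.1-like gene DCAR_016446.v1.0, a partner of nitrate uptake proteins, rose from 0.980 ± 0.651 to 129.9 ± 55.5 FPKM. A cytosolic glutamine synthetase (DCAR_030389.v1.0) fell from 9.78 ± 3.15 to 0.407 ± 0.193 FPKM, and the most abundant one (DCAR_003425.v1.0) was at 617 ± 124 and 633 ± 94.3 FPKM. The median log2 fold change was 0.45, with an adjusted p of 0.0220 by camera (limma with Benjamini-Hochberg) and 0.863 with an estimated correlation.

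Cytochrome P450 genes, oxidases of secondary metabolism, rose in 35 and fell in 14 of 77 tested members, also when adjusted over the list alone, with a median log2 fold change of 0.44. A CYP82H23-like gene (DCAR_001608.v1.0) was listed at 0 in all WT samples and was at 13.8 ± 1.87 FPKM in BC, and a CYP72A219-like gene (DCAR_009787.v1.0) fell from 5.12 ± 0.979 to 0.177 ± 0.306 FPKM. The adjusted p by camera was 0.0282 (limma with Benjamini-Hochberg), and the adjusted p was 0.863 with an estimated correlation. It was 0.0555 with a stricter filter, 0.0990 without numbered IDs, 0.0533 without WT replicate 2 and 0.0581 without BC replicate 2, within a range from 0.00209 to 0.0990 over the settings with the preset correlation (limma with Benjamini-Hochberg).

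Genes that act on toxic compounds and reactive oxygen moved in both directions. Of 50 glutathione genes 22 rose and 6 fell (24 and 8 adjusted over the list alone), including a phospholipid hydroperoxide glutathione peroxidase (DCAR_004643.v1.0) that rose from 25.2 ± 9.48 to 431 ± 57.7 FPKM. Of 32 other scavenging genes 8 rose and 9 fell, also when adjusted over the list alone. Mitochondrial manganese superoxide dismutase (DCAR_010472.v1.0) rose from 124 ± 5.65 to 370.4 ± 29.8 FPKM, and a copper-zinc superoxide dismutase (DCAR_003297.v1.0) fell from 163 ± 45.3 to 6.63 ± 4.14 FPKM. Of 51 UDP-glycosyltransferases 16 rose and 9 fell (17 and 9 adjusted over the list alone), and of 136 vacuolar and ABC transporters 37 rose and 27 fell, also when adjusted over the list alone. With quantile normalization these counts were 11 and 11 and 32 and 32, and with samples rescaled to equal totals 12 and 10 and 29 and 28. Left-out samples moved the glycosyltransferase counts to 10 and 7 (without WT replicate 1) and 10 and 6 (WT replicate 3), and the glutathione counts to 13 and 3 (BC replicate 1). Those of the other scavenging genes moved to 4 and 6 (WT replicate 3), 4 and 8 (BC replicate 1) and 4 and 9 (BC replicate 2). The most abundant transporter family gene, ABC transporter F family member 1 (DCAR_028348.v1.0), fell from 1875 ± 148 to 911 ± 143 FPKM. None of these 4 lists passed camera, the lowest adjusted p being 0.113 for the glutathione list, which passed without BC replicate 3 (adjusted p = 0.0145, limma with Benjamini-Hochberg). With an estimated correlation the glutathione list had an adjusted p of 0.863 by camera.

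Heat shock proteins and chaperones rose in 17 and fell in 33 of 95 tested members (18 and 36 adjusted over the list alone). A BAG family chaperone regulator (DCAR_008644.v1.0) fell from 168 ± 26.1 to 15.7 ± 1.24 FPKM, while a 22.0 kDa heat shock protein gene (DCAR_031996.v1.0) rose from 0.273 ± 0.135 to 38.9 ± 23.7 FPKM. Pathogenesis-related and defence genes rose in 51 and fell in 32 of 152, also when adjusted over the list alone (41 and 37 with quantile normalization, 33 and 25 without WT replicate 3), and a pathogenesis-related protein A-like gene (DCAR_023316.v1.0) fell from 29.3 ± 12.8 to 1.01 ± 0.520 FPKM. The most abundant defence gene, major allergen Api g 1 (novel322), was at 4272 ± 460.5 and 7075 ± 2050.3 FPKM and did not pass the test, except without BC replicate 3 (adjusted p = 0.0247) and under 2 other models of the spread (adjusted p = 0.0489 and 0.0455, limma with Benjamini-Hochberg). Cytosolic ribosomal protein genes rose in 22 and fell in 45 of 187 (17 and 37 adjusted over the list alone), against 11 and 63 with samples rescaled to equal totals and 12 and 72 with quantile normalization. Without WT replicate 1 or 3 or BC replicate 1 or 2 the counts were 10 and 26, 7 and 22, 8 and 36, and 14 and 26. The ribosomal list passed camera as lower with samples rescaled to equal totals (adjusted p = 0.0399), with quantile normalization (0.0317) and without BC replicate 1 (0.0432), against 0.197 as deposited (limma with Benjamini-Hochberg). With an estimated correlation its adjusted p by camera was 0.863.

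In carbohydrate metabolism, 21 of 67 sucrose and hexose genes rose and 19 fell (23 and 20 adjusted over the list alone; 19 and 20 with samples rescaled to equal totals and 20 and 21 with quantile normalization, 15 and 11 without WT replicate 3). Fructokinase-2 (DCAR_028446.v1.0) rose from 181 ± 18.1 to 268 ± 31.9 FPKM, and an ERD6-like 16 sugar transporter (DCAR_002431.v1.0) fell from 23.9 ± 8.18 to 4.02 ± 0.240 FPKM. Starch genes rose in 4 and fell in 11 of 36 (3 and 10 adjusted over the list alone), and a 1,4-alpha-glucan branching enzyme (DCAR_016772.v1.0) fell from 94.99 ± 8.46 to 42.3 ± 1.64 FPKM. The member of the starch list with the largest rise (DCAR_026808.v1.0) is an amylase and subtilisin inhibitor, not an enzyme of starch. Cell wall loosening and pectin genes rose in 31 and fell in 16 of 111, also when adjusted over the list alone (29 and 22 with quantile normalization). A xyloglucan endotransglucosylase (DCAR_029555.v1.0) rose from 7.25 ± 1.43 to 81.9 ± 21.02 FPKM, and an endoglucanase 25-like gene (DCAR_004901.v1.0) fell from 17.3 ± 2.99 to 0.0633 ± 0.0115 FPKM. Cellulose and xylan genes rose in 11 and fell in 3 of 32 (9 and 3 adjusted over the list alone), against 6 and 3 without WT replicate 1, WT replicate 3 or BC replicate 1. Starch counts were 3 and 7 without WT replicate 1, 3 and 4 without WT replicate 3, 3 and 5 without BC replicate 1 and 3 and 6 without BC replicate 2. None of these 4 lists passed camera, the lowest adjusted p being 0.153 for the cellulose and xylan list (limma with Benjamini-Hochberg).

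Hormone genes changed in both directions. Ethylene genes rose in 38 and fell in 17 of 101 (42 and 17 adjusted over the list alone, 25 and 13 without WT replicate 3), with 1-aminocyclopropane-1-carboxylate oxidase (DCAR_019257.v1.0), which makes ethylene, rising from 45.97 ± 4.70 to 341 ± 120.2 FPKM. Auxin genes rose in 22 and fell in 15 of 79 (22 and 16 adjusted over the list alone), and IAA7-like DCAR_030713.v1.0 rose from 7.07 ± 4.43 to 52.5 ± 10.3 FPKM. Gibberellin and cytokinin genes rose in 13 and fell in 22 of 63, also when adjusted over the list alone. Gibberellin-regulated protein 6-like DCAR_011097.v1.0 fell from 1349 ± 146 to 201 ± 51.3 FPKM, and gibberellin-regulated protein 11-like novel1871 rose from 169.8 ± 72.7 to 1149 ± 520.5 FPKM. Jasmonate genes rose in 4 and fell in 3 of 17, also when adjusted over the list alone, and the median (-0.04) and mean (0.14) log2 fold change of that list differed in sign, with 3 higher and 5 lower when samples were rescaled to equal totals. Senescence and water deficit genes rose in 28 and fell in 19 of 118 (26 and 18 adjusted over the list alone), against 21 and 22 with samples rescaled to equal totals and 20 and 26 with quantile normalization. They were 18 and 15, 16 and 13, and 19 and 12 without WT replicate 1, WT replicate 3 and BC replicate 1. No hormone list passed camera, the lowest adjusted p being 0.152 for ethylene (limma with Benjamini-Hochberg).

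MYB and bHLH transcription factors rose in 30 and fell in 25 of 116 (30 and 26 adjusted over the list alone), against 26 and 28 with samples rescaled to equal totals and 22 and 27 with quantile normalization. WRKY and NAC factors rose in 27 and fell in 12 of 73 (27 and 13 adjusted over the list alone), against 19 and 15 with quantile normalization and 13 and 11 with the stricter filter. They were 21 and 6 without WT replicate 3 and 20 and 7 without BC replicate 1. WRKY 40 (DCAR_025562.v1.0) rose from 0.403 ± 0.307 to 7.13 ± 2.33 FPKM, and MYB1R1-like DCAR_004992.v1.0 fell from 642 ± 82.7 to 403 ± 23.1 FPKM. Histone and cell cycle genes rose in 35 and fell in 19 of 143 (32 and 17 adjusted over the list alone), against 26 and 21 with samples rescaled to equal totals, 20 and 11 without WT replicate 3 and 19 and 12 without BC replicate 1. These 3 lists had adjusted p of 0.645, 0.266 and 0.232 by camera (limma with Benjamini-Hochberg).

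None of the 4 lists of markers for cell types of the root passed camera. Periderm and suberin genes rose in 6 and fell in 3 of 14 (7 and 5 adjusted over the list alone). Xylem genes rose in 3 and fell in 3 of 13 and phloem genes rose in 4 and fell in 8 of 25, both also when adjusted over the list alone. Cambium and meristem genes rose in 5 and fell in 2 of 20 (4 and 2 adjusted over the list alone), against 4 and 4 with samples rescaled to equal totals and 3 and 3 with quantile normalization. Cambium counts were 3 and 2 without WT replicate 1 or BC replicate 1 and 3 and 1 without WT replicate 3. Phloem counts were 2 and 8 rescaled, 2 and 4 without WT replicate 3 and 3 and 5 without BC replicate 1. Xylem counts were 3 and 5 with quantile normalization. The abundant phloem protein 2-like gene novel558 fell from 419 ± 247 to 40.7 ± 29.7 FPKM, and the phloem list had a median log2 fold change of 0.05 and a mean of -0.51. This gene and novel381, named above among the largest falls, matched the same RefSeq gene. WUSCHEL-related homeobox 4 (DCAR_019432.v1.0), a regulator of the cambium, rose from 9.68 ± 3.96 to 37.1 ± 16.3 FPKM. The lowest adjusted p of these lists by camera was 0.511, for periderm and suberin (limma with Benjamini-Hochberg), and the xylem list had a median of -0.0033 and a mean of 0.13. For the cambium list the median was 0.10, while fry leaned the other way without passing (adjusted p = 0.861, limma with Benjamini-Hochberg).

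**Figure D3:**
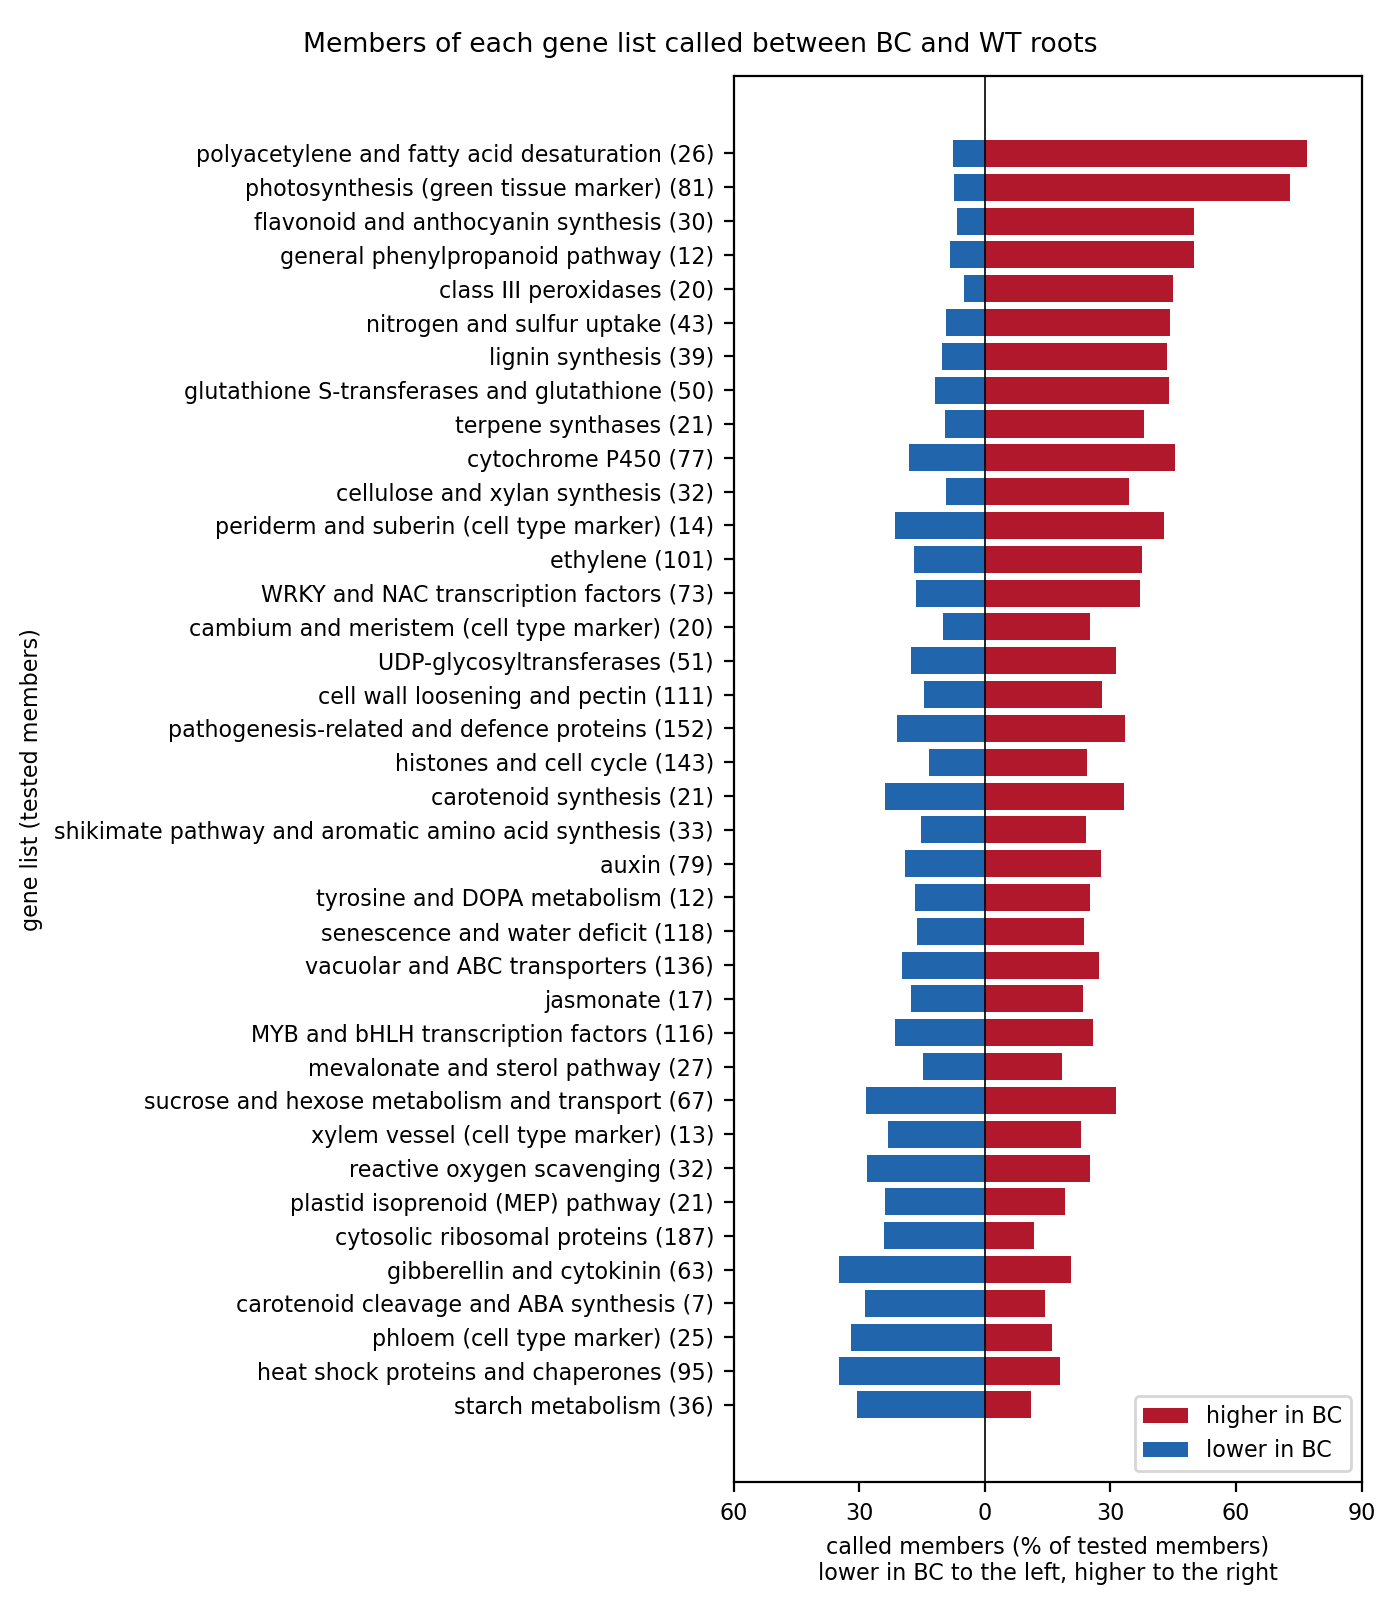
Share of tested members of each of 38 gene lists called higher (red, right) or lower (blue, left) in BC roots, in percent of the tested members, whose number stands in brackets. In the photosynthesis list 59 of 81 members were higher and 6 lower, and in the starch list 4 of 36 were higher and 11 lower.

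The annotation terms in the table were tested too. Of 637 terms tested in each direction by one-sided Fisher's exact tests with Benjamini-Hochberg adjustment, 47 held more of the higher genes and 25 more of the lower genes than the 15091 annotated tested genes did. Photosystem II held 35 higher genes among 46 (adjusted p = 7.41e-12, Fisher's exact test), phenylpropanoid biosynthesis 58 among 122 (adjusted p = 7.09e-08) and biosynthesis of unsaturated fatty acids 27 among 46 (adjusted p = 8.24e-06). Phosphate ion transport held 62 higher genes among 167 and glutathione metabolism 31 among 80. The spliceosome, the complex that removes introns, held 105 lower genes among 216 (adjusted p = 5.21e-14, Fisher's exact test), RNA processing 35 among 66, aminoacyl-tRNA biosynthesis 27 among 59 and the plant circadian rhythm 19 among 41. With only the genes changed at least 2-fold, 10 terms held more of the lower genes. Fisher's test takes the genes of a term as independent, so its p-values are too small where genes move together. The terms were not tested with an estimated correlation, under which 0 of the 38 lists passed camera, nor on other splits of the samples.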

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

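Fits without genes read in one group only and without genes with numbered IDs were chosen after seeing the data. Across all settings the number of genes called stayed within 1.5 times 9749, from 6639 without WT replicate 3 to 10329 with quantile normalization. The number lower in BC ranged from 3193 (without WT replicate 3) to 5203 (without BC replicate 3) when a sample was left out, the latter above the 4943 of the whole fit. With a pseudocount of 5, which shrinks changes of low genes, 2304 genes changed at least 2-fold, 1484 higher and 820 lower, and with the stricter filter, which tests fewer genes, 1749 were at least 2-fold higher. Rescaling to equal totals moved the median of all genes from -0.02 to -0.11.

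With the correlation estimated per list, 0 of 38 lists passed camera in limma (0 also at an unadjusted p under 0.05, against 14 that fry called as moving one way), and those called before had medians of 1.23 (photosynthesis), 1.15 (fatty acid desaturation), 0.69 (flavonoid), 0.57 (lignin), 0.45 (nitrogen and sulfur) and 0.44 (cytochrome P450). Lists lower in BC numbered 1 with rescaling to equal totals and 1 with quantile normalization, and 0 to 1 with a sample left out. Lignin lost its call with the stricter filter (0.28) and without numbered IDs (0.51), and ranged from 0.49 to 0.66 with a sample left out. Cytochrome P450 lost its call with the stricter filter (0.25) and without numbered IDs (0.26), and ranged from 0.40 to 0.71. Terms lower in BC numbered 10 with genes changed at least 2-fold. Apart from the constructions named, the cause was not tested.

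Of 2466 values of 140 named genes under other settings, 2349 kept their direction and side of the threshold, 89 lost the call, 13 gained it and 15 reversed, and 101 of 123 called genes kept their call throughout. The reversals were in genes that were not called. DCAR_003425.v1.0 was at -0.057 rescaled to equal totals and -0.096 with quantile normalization, DCAR_010571.v1.0 at -0.060 rescaled, DCAR_029673.v1.0 at -0.045 and -0.025, and novel1853 at 0.0074 with size factors. With a sample left out DCAR_003425.v1.0 ranged from -0.11 to 0.18, DCAR_024648.v1.0 from -0.14 to 0.059, DCAR_029673.v1.0 from -0.0065 to 0.10 and novel1853 from -0.087 to 0.13.

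Whether the replicate numbers shared between the groups pair the samples is not given in the labels. Deviations of same-numbered samples from their group means correlated at 0.20, -0.36 and -0.20, which does not settle it. With the replicate block 7953 genes were called, 4032 higher and 3921 lower. Unknown read depth limits what can be said of genes listed at 0.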

Other observations

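The tests on clock genes, and the gene groups in the next paragraph, were chosen after their values were seen, while the other tests of this section were fixed before the values they measure.

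Of 21 acid phosphatases, enzymes that release phosphate, 11 rose and 1 fell in BC, with purple acid phosphatase 8-like DCAR_023545.v1.0 rising from 4.75 ± 3.72 to 46.8 ± 5.10 FPKM, and of 7 SPX domain genes 3 rose and 1 fell. Of 26 extensin genes 11 rose and 7 fell, so that the rises of the 2 most changed ones were not shared by the whole family. Among light-signalling genes HY5 (DCAR_003095.v1.0), a promoter of light responses, rose from 9.03 ± 1.94 to 29.8 ± 5.999 FPKM and phytochrome A (DCAR_001880.v1.0) fell from 91.2 ± 12.6 to 40.8 ± 6.54 FPKM. Of 26 B-box and CONSTANS-like genes 10 rose and 8 fell. Among those that rose, DCAR_007535.v1.0 and DCAR_007537.v1.0 had the same values in all samples.

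Clock genes filed as morning or evening genes by their known peak mostly moved in opposite directions, in lists settled after some values were seen. Of 6 morning genes 4 rose and 1 fell (LHY, DCAR_006991.v1.0, from 133 ± 16.0 to 229 ± 50.8 FPKM), and of 7 evening genes 6 fell and 0 rose (GIGANTEA, DCAR_001164.v1.0, from 36.8 ± 9.51 to 11.4 ± 0.964 FPKM), so that their median log2 fold changes, 1.02 and -1.35, lay 2.37 apart. This distance was at least 2.29 under other scalings, a void check since these shift all genes nearly alike. A harvest of the groups at different times of day may account for it, as may an effect of the genotype on the clock, which was not tested and which the labels, with no hour of harvest, leave open. Genes of the daytime were left out of the lists after some of their values had been seen and went both ways, with 2 of 5 higher (LNK2, DCAR_003244.v1.0, 2.53) and 1 lower (an APRR7 gene, DCAR_017720.v1.0, -1.92), so the distance comes from genes chosen for the pattern and gives no support to either explanation.

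A set of 261 genes was at 5 FPKM or more in all samples of one group and at 0.1 FPKM or less in all of the other, 170 of them in BC and 91 in WT. The set takes in many genes named above for large rises and falls. The FAD2-like DCAR_013549.v1.0, CYP82H23-like DCAR_001608.v1.0 and endoglucanase 25-like DCAR_004901.v1.0 genes are also in it. Noise at low levels is argued against by the other splits of the samples, which gave at most 2 such genes. A shift of reads between near-identical copies was tested on the 102 of them with a protein match. Of these, 4.90% had a partner on the same protein called in the opposite direction, against 1.46% among other called genes. Genes with no other gene on their protein entry counted as having no partner, so a low share was partly set by the annotation. The share also lay above that of other called genes, so the test does not decide whether reads shifted. Copies matched to different entries, such as isoforms, were not counted, and the rest of the set was not tested. The AGL27 genes named above, described as isoforms X1 and X2, moved in opposite directions. Genes of the set had another one among the 3 nearest placed genes to each side in 7 cases, against a median of 2 in 10000 random draws (permutation p = 0.0055). This could come from BC and WT plants that differ in stretches of genome sequence. That test rests on 55 placed genes, only 2 of its 5 neighbouring pairs had the same direction, and a direct effect of the genotype stays open. Genes with numbered IDs in place of locus IDs made up 54.0% of the set and 11.03% of the other genes at that level.

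For the photosynthesis genes, scaling is argued against by a median log2 fold change of at least 1.04 under the other scalings, and a single BC library by a median of at least 1.14 when any BC sample was left out. Shoot tissue in the BC samples was tested on 19 shoot identity genes, whose median was -0.31, with 4 higher and 6 lower. Those that rose included EPIDERMAL PATTERNING FACTOR-like genes (DCAR_003495.v1.0, log2 fold change 1.51, and DCAR_027242.v1.0, 1.195) and a KAN1-like gene (DCAR_014150.v1.0, 1.06). Those that fell were mostly growth-regulating factors, such as DCAR_008187.v1.0 (-0.78), and included a TCP4-like gene (DCAR_021280.v1.0, -1.22). The median of the 19 genes therefore mixed genes that moved in opposite directions. Among the most abundant, a growth-regulating factor 1-like gene (DCAR_020065.v1.0) fell from 48.9 ± 0.712 to 14.01 ± 5.19 FPKM, a TCP4 gene (DCAR_019587.v1.0) rose from 41.97 ± 5.72 to 61.4 ± 10.6 FPKM, and stomatin-like protein 2 (DCAR_008993.v1.0), a mitochondrial protein caught by the wording, fell from 58.8 ± 2.69 to 49.3 ± 1.42 FPKM. The bound set beforehand would have excluded shoot tissue at this value, but it was wrongly chosen and was set aside after the value was seen, because only 1 of these genes was below 1 FPKM in WT (median 8.78 FPKM), so that a small share of shoot cells would be hidden. Shoot tissue and a response of the root itself to light or genotype therefore cannot be told apart here. A difference in the hour of harvest, raised above for the clock genes, was not tested for the photosynthesis genes and stays open too.

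Of 216 spliceosome genes 105 fell and 12 rose, with a median of -0.30 that was at most -0.28 under other scalings. Fold changes showed a trend on gene span across the 70.0% of tested genes with a span. In sets of rising span, the median log2 fold changes were 0.19, 0.02, -0.05 and -0.12. Over the 78.7% of spliceosome genes with a span, the median was -0.26 before and -0.23 after this trend was removed. That check is void because fewer than 80% had a span, so it does not decide whether the trend lowered these genes. No other list, photosynthesis included, was checked against the trend.

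The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split called 9749 genes and 4183 at least 2-fold (1 of 10 splits with as many). The highest of the others called 1 gene in both cases. Every other split mixes BC and WT samples, so the group difference entered its spread and few calls were bound to follow. These gene counts therefore do not bear on chance or on false calls. For gene lists 7 of the 10 splits, the real one included, gave as many as the real 6, the highest of the others being 11. Mixed splits still carry part of the group difference, so the list count does not measure chance either.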
